A study of Mus musculus with 6 samples.

How the data were processed

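Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on mouse epididymal adipose tissue taken 4 weeks after intraperitoneal injection of an adeno-associated virus carrying Flag-tagged Otud3. Per the labels, 3 libraries were immunoprecipitated with an antibody against the Flag tag and 3 libraries were input DNA, numbered 1, 3 and 4 in each group. The labels give a read length of 75 bp and name both single-end and paired-end sequencing, so the layout is left open. They do not say whether the libraries came from separate animals, and the spread between them may therefore be technical.

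The deposited files are 3 peak lists, 1 for each immunoprecipitated library, in coordinates of mouse build mm10. Per the submitters' processing notes, fastp 0.19.11, BWA 0.7.12 and MACS2 2.1.0 were used. Replicates were not pooled in these lists. Whether each list was called against its input is not given in the sources used here, and values of the 3 input libraries were not analysed here. Each peak has a fold enrichment ratio over the local background, a −log10 p-value and a −log10 q-value, all from the authors' peak caller, together with an integer score derived from them in the deposited lists. These are the authors' values and served only to describe, rank or filter peaks within their own list. Several summits inside 1 interval were reduced to the summit with the lowest p, which left 11871, 6531 and 13496 distinct intervals.

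Read totals are not given in the lists, so depth was read from the peaks. The caller's fold is the number of fragments at the summit plus a pseudocount of 1, divided by the background plus 1, and its p is a Poisson tail, so the fold and p of a peak fix both quantities. A whole number of fragments matched the p to within 0.001 on the log10 scale for 100% of the peaks in each list. With the p-values permuted among the peaks of a list, 6.58%, 2.98% and 4.64% matched. The lowest background was 0.407, 1.17 and 0.839 fragments per position in replicates 1, 3 and 4, after any scaling between libraries by the caller, so replicate 3 had the highest effective depth and replicate 1 the lowest. The fragments behind a peak are counts, and a peak of 4 to 6 fragments carries a large counting error.

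A region was shared when peaks of different lists overlapped by at least 1 bp. Overlap was tested against 1000 random placements of the peaks on their own chromosome, between its first and last peak, one-sided, with a smallest possible p of 0.001. The same placements gave a two-sided test of where summits lie, with a smallest possible p of 0.002 and Benjamini-Hochberg adjustment over 24 tests. Gene positions came from a RefSeq table of build GRCm38.p6, the build that mm10 names, with 21887 protein-coding genes. The table holds gene starts and ends without strand, transcription start sites or exons. The planned window around transcription start sites therefore became 1 kb around either annotated gene end, and exons, introns and untranslated regions were not told apart. The 16 motifs, the repeat mask and promoter CpG content need genome sequence and were not analysed here.

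Before the data were examined, 21 gene lists were fixed for adipose metabolism, signalling, transcriptional regulators and cell type markers, and 2 of their gene symbols had no match in the table. Lists were tested by Fisher's exact test at gene ends. In the gene body with 5 kb either side they were tested against 10000 random lists matched on gene length in 25 bins. Both tests were two-sided, with adjustment over the 21 lists of a library and over the 63 tests of 3 libraries. The genes named were to be the 15 with a region of all 3 lists at a gene end and the highest mean within-list percentile of fold, up to 3 members of each fixed list, and Otud3. No such region lay on a gene, so the rule's last step applied, which takes genes with a region in 2 of the 3 lists. Of these genes, 1 that the rule takes is not reported here. Other genes named below were chosen after their values were seen, and are given as such.

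The alternatives fixed beforehand were a q of at most 1e-05, a fold of at least 5, chromosomes 1 to 19, X and Y alone, 50% reciprocal overlap, summits within 100 bp, regions of at least 2 lists, leaving out each replicate, placement within 50 kb, a 3 kb window and gene bodies. With 1 group measured, no comparison between groups was made. The procedures were tested on simulated data. Of 60 regions planted in 3 randomly placed lists of 31898 intervals in all, 60 were recovered, and 0 were found with none planted. The planted peaks began at the same position in every list, so this checked the counting of overlaps alone. It did not test whether weak shared sites would be called. The length-matched test called 1 list when 1 was planted and 0 when hits followed gene length alone, over 21887 genes. The planted list was that of the adipogenic transcription factors, with most of its genes set as hit, in 1 draw. Each gene was drawn on its own, so peaks clustered along the genome and a weaker excess were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.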

Results

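Binding of Flag-tagged OTUD3 to chromatin was profiled in mouse epididymal adipose tissue. OTUD3 is a deubiquitinase of the ovarian tumour family, an enzyme that removes ubiquitin from proteins, and it was supplied by an adeno-associated virus of serotype 2. Peak lists of 3 anti-Flag libraries, numbered 1, 3 and 4, entered the comparisons, and the 3 input libraries were not analysed here. All positions are on mouse build mm10. The question put to the lists was where tagged OTUD3 was enriched on the genome and whether the libraries shared those sites.

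Peaks were numerous in all 3 libraries and weak in nearly every case. The lists held 11876, 6541 and 13503 peaks in replicates 1, 3 and 4 (mean 10640 ± 3642 SD, n = 3), covering 3.50, 1.999 and 3.92 Mb. The caller's fold enrichment had a median of 3.20, 3.00 and 2.99, and the summit of the median peak rested on 4, 6 and 5 fragments. At a q below 0.05 there were 40, 26 and 69 peaks, or 0.337%, 0.397% and 0.511% of each list. The largest p of any peak was close to 0.005 in every list, and 83.9%, 91.2% and 93.2% of peaks had a q above 0.5. Only 10, 7 and 26 peaks remained at a q of at most 1e-05, and 31, 9 and 17 at a fold of at least 5. With so few fragments per peak, enrichment at a single site was mostly not distinguishable from background at this depth.

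Of the peaks with a q below 0.05, 13, 13 and 34 lay in the blocks shared by all libraries described below, on unplaced scaffolds or on the mitochondrial genome, where 4 came from replicate 3. The other 27, 13 and 35 peaks had a median fold of 5.602, 5.06 and 4.98, with lowest folds of 2.28, 4.88 and 1.43. Of these 75, 36 lay on or within 1 kb of a protein-coding gene. Gene ends had 5 of the 27 in replicate 1, 0 of 13 in replicate 3 and 0 of 35 in replicate 4. The 5 are named here after their values were seen. These were Mrnip, a factor in DNA double-strand break repair, Zfand5, a zinc finger protein that binds ubiquitin, and the immediate-early genes Dusp1, Klf4 and Zfp36. Dusp1 encodes a phosphatase of MAP kinases, and its peak on chromosome 17 at 26507734 to 26508312 had a fold of 5.69 from 7 fragments (q = 0.0132). Klf4 encodes a Krüppel-like transcription factor, and its peak on chromosome 4 at 55531901 to 55532175 had a fold of 5.83 from 8 fragments (q = 0.00824). Zfp36, the gene of the mRNA-destabilising protein tristetraprolin, had a fold of 5.38 from 7 fragments (q = 0.0294). In replicate 4 a peak inside Atm, the kinase of the DNA damage response, on chromosome 9 at 53451487 to 53451752 had a fold of 6.69 from 20 fragments (q = 2.02e-08), also chosen after its value was seen. None of these genes had an overlapping peak at that site in another list. Of the 75 peaks, 6 overlapped another list (0, 1 and 5 in replicates 1, 3 and 4), and the chromosome 17 site below is counted in both replicates 3 and 4. Some of those in replicate 4 had a low fold and high coverage, like the shared blocks. Examples are chromosome 14 at 19415734 (fold 1.45, 237 fragments) and chromosome 9 at 35305200 (fold 1.43, 377 fragments). A site on chromosome 17 at 4626108 to 4626559, also chosen after its values were seen and away from genes, had a fold of 5.66 from 66 fragments in replicate 3 (q = 6.68e-23) and an overlapping peak of fold 2.01 from 126 fragments in replicate 4 (q = 2.58e-07).

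Sites found in all 3 libraries were few and lay away from genes. They numbered 13, against 0.107 ± 0.343 (SD of 1000 random placements) expected by chance (permutation p = 0.001, one-sided, the smallest possible). Placement within 50 kb gave 2.09 ± 0.955 (permutation p = 0.001). On chromosome 9, 10 of them fell between 3000207 and 3035273, with Alkbh8, a tRNA methyltransferase gene, the nearest at 299.958 kb. On chromosome 2, 2 fell between 98662218 and 98667326, with Lrrc4c, a gene of a synaptic adhesion protein, the nearest at 1031 kb. The last lay on the unplaced scaffold JH584304.1. Both chromosomal blocks belong to the stretches of mm10 that are commonly masked in ChIP-seq because reads from repeated sequence pile up there.

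Enrichment at these 13 regions was low and coverage high. The mean fold over the libraries was 1.503 ± 0.143 on chromosome 9 and 1.38 ± 0.0341 on chromosome 2 (SD, n = 3), and 1.72 ± 0.195 on the scaffold. Summits there held a median of 363, 401 and 409 fragments, or 90.8, 66.8 and 81.8 times the median of the list. The blocks were drawn around the chromosomal regions, so all 13 lay in these blocks or on this scaffold by construction.

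Regions of at least 2 lists numbered 142, against 82.1 ± 8.94 expected (permutation p = 0.001, one-sided, the smallest possible). Replicates 1 and 3 shared 52 regions, replicates 1 and 4 shared 67, and replicates 3 and 4 shared 49, against 21.2, 39.3 and 21.8 expected (each permutation p = 0.001). Placement within 50 kb gave 111.7 regions of at least 2 lists (permutation p = 0.001) and 33.3, 52.1 and 30.6 for the pairs (permutation p = 0.002, 0.03 and 0.002). With the blocks and 50 kb either side, unplaced scaffolds and the mitochondrial genome left out, a setting chosen after seeing the data, 121 regions of at least 2 lists were left, against 79.2 expected with placement anywhere on the chromosome and 103.8 with placement within 50 kb (permutation p = 0.001 and 0.049). With placement within 50 kb, the pairs outside the blocks gave 36 regions for replicates 1 and 3 (29.2 expected, permutation p = 0.128), 51 for replicates 1 and 4 (48.9 expected, p = 0.401) and 34 for replicates 3 and 4 (26.2 expected, p = 0.0849). With placement anywhere on the chromosome, 19.4, 38.5 and 21.5 were expected for these pairs (permutation p = 0.001, 0.03 and 0.004). Outside the blocks, 1.04%, 1.103% and 0.504% of the peaks in the highest quartile of fold in replicates 1, 3 and 4 overlapped another list, and 0.883%, 0.995% and 0.869% of those in the lowest quartile, a difference that was not tested.

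A region of 2 lists lay on or within 1 kb of 83 protein-coding genes, 16 of them at a gene end, and the 15 ranked highest by the percentile of fold had 13 regions with folds of 3.07 to 4.98 from 4 to 9 fragments. Each of these regions was seen in 2 of the 3 libraries and no peak among them had a q below 0.05, with q from 0.0541 to 0.950. Junb, an AP-1 transcription factor, had a region at its gene end on chromosome 8 at 84977360 to 84978110, with a fold of 4.98 in replicate 1 and 3.23 in replicate 3. Rela, the p65 subunit of NF-κB, had a region on chromosome 19 at 5646830 to 5647236, with folds of 3.98 and 3.55 in the same libraries. Kdm6b, a histone H3 lysine 27 demethylase, shared a region with its neighbours Tmem88 and Naa38 on chromosome 11 at 69397637 to 69398348, with folds of 3.79 in replicate 1 and 3.46 in replicate 4. Another shared region lay inside the body of Kdm6b, at 69407419 to 69408101. Its folds were 4.14 in replicate 1 (q = 0.342) and 3.00 in replicate 3 (q = 0.950). Ino80, the ATPase of a chromatin remodelling complex, had a region in its body on chromosome 2 at 119412512 to 119413359, with folds of 3.68 in replicate 3 and 4.09 in replicate 4. Zfp831, a zinc finger gene, ranked first with folds of 4.27 in replicate 1 and 4.03 in replicate 3 inside its body on chromosome 2.

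Among the same 15, Ifitm3, an interferon-induced membrane protein gene, had folds of 4.27 and 3.19 in replicates 1 and 3, and H2-K1, a class I histocompatibility gene, had folds of 3.65 and 3.07 in replicates 3 and 4. Fads6, a gene of the fatty acid desaturase family, had folds of 4.05 in replicate 1 and 4.81 in replicate 4, inside its body on chromosome 11 at 115283470 to 115283831. Also in this set were Stx8, a gene of endosomal membrane fusion, with folds of 3.65 and 4.35 in replicates 3 and 4, Fsd1l with 3.79 and 3.26 in replicates 1 and 4, Wwox, an oxidoreductase gene, with 3.68 and 3.12 in replicates 3 and 4, and Serpina3j, a serpin gene, with 3.32 and 3.77 in replicates 1 and 4.

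From the fixed gene lists, 2 members had such a region. Insr, the insulin receptor, had one at its gene end on chromosome 8 at 3151579 to 3151840. Its folds were 2.53 from 3 fragments in replicate 1 (q = 0.992) and 3.16 from 6 fragments in replicate 3 (q = 0.950). Acacb, the acetyl-CoA carboxylase isoform that restrains mitochondrial fatty acid import, had one inside its body on chromosome 5 at 114172912 to 114173355, with folds of 2.27 in replicate 3 (q = 0.745) and 3.48 in replicate 4 (q = 0.0192). Otud3 itself, on chromosome 4 from 138891063 to 138914026, had 0 peaks in all 3 lists. The nearest peaks lay 44.7, 28.1 and 55.4 kb away in replicates 1, 3 and 4. The injected vector carries Otud3 coding sequence, whose reads can map to the exons of this gene. Exon positions were not available, but with 0 peaks in the whole gene the planned count over its exons is 0 in every list.

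Peaks lay within 1 kb of gene ends more often than with placement on the chromosome in replicates 1 and 3, and replicate 4 did not pass. The share of summits within 1 kb of either annotated end of a protein-coding gene was 6.05% in replicate 1, 4.11% in replicate 3 and 3.00% in replicate 4, against 3.21%, 3.14% and 3.12% for random placement on the chromosome. Permutation p was 0.002 in replicates 1 and 3, the smallest possible (adjusted p = 0.00436 in both), and 0.460 in replicate 4 (adjusted p = 0.525). The shares differed between every pair of lists (Fisher's exact test over peaks, adjusted p = 2.27e-08 for replicates 1 and 3, 1.29e-31 for 1 and 4, and 5.79e-05 for 3 and 4), a comparison of these lists alone. Against placement within 50 kb, which keeps the gene-rich surroundings, the expected shares were 5.01%, 4.48% and 3.75%. Replicate 1 then stayed above (permutation p = 0.002), replicate 3 fell on the other side without passing (p = 0.150) and replicate 4 lay below (p = 0.002). With a 3 kb window, replicate 4 lay above placement on the chromosome, at 9.13% against 8.40% (permutation p = 0.006), and below placement within 50 kb, at 10.04% (permutation p = 0.002), a pairing chosen after seeing the data.

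**Figure D1:**
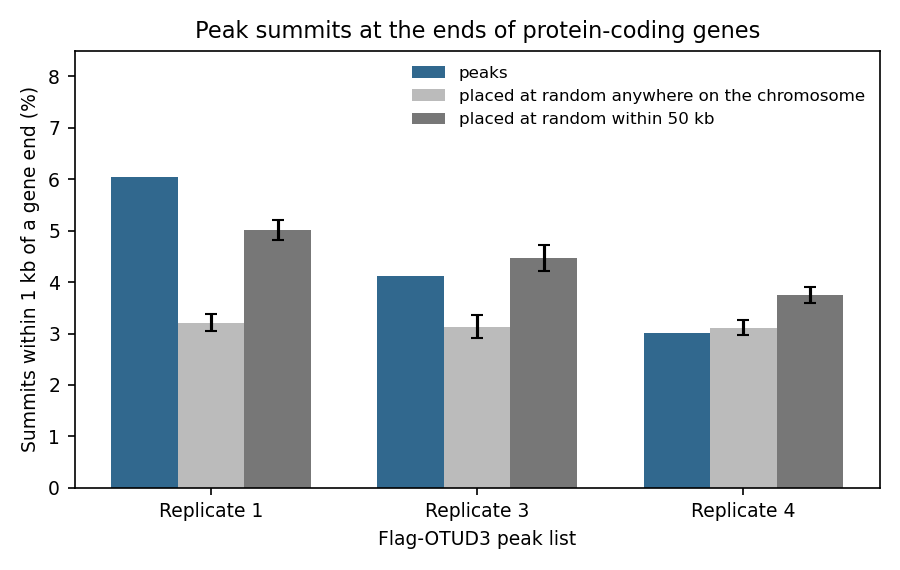
Share of peak summits within 1 kb of either end of a protein-coding gene, in percent, for the 3 peak lists, beside the mean share for the same peaks placed at random 1000 times anywhere on the chromosome or within 50 kb (error bars, SD of the placements). Replicate 1 stands at 6.05%, above both, and replicate 4 at 3.00%, below the 3.75% of placement within 50 kb.

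Gene bodies outside the end windows held 47.5%, 51.6% and 47.2% of summits in replicates 1, 3 and 4, which was 1.201, 1.31 and 1.201 times the share with placement on the chromosome (each permutation p = 0.002, the smallest possible). With placement within 50 kb the ratios were 1.00, 1.05 and 1.04 (permutation p = 0.559, 0.002 and 0.002). A peak in the gene body or within 1 kb was found in all 3 lists for 854 of 21887 genes, whose median length was 201 kb against 17.2 kb for all genes. Placement on the chromosome gave 619.9 such genes (permutation p = 0.001) and placement within 50 kb gave 823.9 (permutation p = 0.036).

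At the ends of the fixed lists' genes, no list passed. The 13 regions of all 3 libraries touched 0 members of the 21 lists. With each library on its own, 7 of 63 tests had an unadjusted p below 0.05 and 0 passed after adjustment (Fisher's exact test, lowest adjusted p = 0.403 over 63 tests). The lists with a low unadjusted p in the exact test were PPAR and coactivator regulators with 4 of 28 genes in replicate 1 (p = 0.0242), lipolysis and fatty acid oxidation with 4 of 32 in replicate 1 (p = 0.0375), adipogenic transcription factors with 3 of 20 in replicate 1 (p = 0.0437), oxidative phosphorylation with 4 of 59 in replicate 3 (p = 0.0131), the TCA cycle with 2 of 17 in replicate 3 (p = 0.0278), insulin and adipokine signalling with 2 of 22 in replicate 3 (p = 0.0448), and heat shock with 2 of 15 in replicate 4 (p = 0.0446).

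In gene bodies with 5 kb either side, genes of adipogenic transcription factors carried peaks more often than genes of their length in replicates 1 and 3 when this set of tests was adjusted on its own. In replicate 1, 15 of 20 were hit, against 7.66 ± 1.91 for length-matched random lists (permutation over genes of like length, two-sided, adjusted p = 0.0084 over the library's lists and 0.0252 over 63 tests). In replicate 3, 12 of 20 were hit, against 5.47 ± 1.78 (permutation, adjusted p = 0.0294 and 0.0441). Replicate 4 had 10 of 20, against 7.99 ± 1.78 (permutation p = 0.387, adjusted p = 1), and the difference between libraries was not tested. Applying gene bodies to each library was chosen after the regions of all 3 lists had given 0 genes, as a further set of 63 tests beside the 63 at gene ends. Of these tests 6 had an unadjusted p below 0.05, and the 2 above passed after adjustment over these 63. Over both sets together, 126 tests, 0 passed (permutation, adjusted p = 0.0504 and 0.0882 for the 2), an adjustment chosen after seeing the data. The count was not above placement within 50 kb after adjustment in replicates 1 and 3, where 12.1 and 9.34 genes were expected (permutation, adjusted p = 1 and 0.713). Unadjusted, the same permutation gave p = 0.0719 and 0.034. That placement can keep a peak on a gene as long as many of these are, which may lower its power. The power was not measured. Neither call passed in the peaks above the median fold (10 and 6 genes against 4.72 and 3.21 expected, permutation, adjusted p = 0.132 and 0.757), nor that of replicate 3 with the gene body alone (10 genes against 4.96, permutation, adjusted p = 0.126), while each count stayed above its expected value.

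The genes named from this list and from the lists that follow were chosen after their hits were seen. Of these 20 genes, 7 were hit in all 3 libraries: Ebf1 and Ebf2, early B-cell factors that act in adipocyte differentiation, Zfp423, a determinant of the preadipocyte fate, Creb1, a cyclic AMP response factor, Stat5b, a transducer of growth hormone signals, Nfia, a nuclear factor I gene, and Tcf7l1, a Wnt pathway factor. They span 71.8 kb (Creb1) to 541 kb (Nfia), and Ebf1, of 390 kb, held 4, 1 and 4 peaks in replicates 1, 3 and 4. Pparg, the master regulator of adipogenesis, and Cebpa, its partner, were hit in replicates 1 and 3 and not in replicate 4. Atf4 and Cebpd, short genes of 2.36 and 2.26 kb, were hit in none.

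Among the other metabolic lists, PPAR and coactivator regulators had 19, 13 and 15 of 28 genes hit in replicates 1, 3 and 4, against 12.3, 8.76 and 13.1 matched (permutation, adjusted p = 0.113, 0.547 and 1), including Ppargc1a and Prdm16 in all 3. Lipogenesis and cholesterol had 12, 11 and 11 of 26 (8.25, 5.45 and 8.22 matched, permutation adjusted p = 0.498, 0.123 and 1), with Acaca, Abca1 and Abcg1 in all 3. Lipolysis and fatty acid oxidation had 14, 5 and 11 of 32 (7.79, 4.60 and 6.89 matched, permutation adjusted p = 0.157, 1 and 1), with the fatty acid transporter Cd36 in all 3. Hits in all 3 libraries were not particular to these lists. Among PPAR regulators, lipogenesis and lipolysis genes they covered 3 of 28, 3 of 26 and 1 of 32. Of the 12 neuronal genes, a tissue control, 2 were also hit in all 3 libraries, Syt1 and Rbfox3. Heat shock and unfolded protein genes had 5, 5 and 4 of 15 (2.62, 1.42 and 2.03 matched, permutation adjusted p = 0.498, 0.123 and 1). Insulin and adipokine signalling had 9, 7 and 7 of 22 (8.05, 5.52 and 8.42 matched), glucose uptake and glycolysis 9, 3 and 3 of 28 (7.11, 4.11 and 6.44), the TCA cycle 7, 5 and 4 of 17 (4.54, 2.67 and 4.12), and oxidative phosphorylation 8, 8 and 8 of 59 (10.2, 5.19 and 7.16). OTU deubiquitinases and interacting ligases had 3, 0 and 4 of 13 (3.43, 2.14 and 3.17 matched), and cytosolic ribosomal proteins 4, 1 and 4 of 40 (4.78, 2.37 and 3.10).

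Marker genes of other cell types did not pass in any library. Macrophage markers had 5, 3 and 4 of 15 genes hit (4.09, 2.76 and 3.96 matched), endothelial markers 7, 1 and 2 of 10 (4.21, 2.95 and 4.43), progenitor and fibroblast markers 4, 2 and 4 of 11 (3.13, 1.90 and 2.92), and lymphocyte markers 3, 0 and 1 of 12 (1.97, 1.01 and 1.45). Mesothelial markers had 1, 1 and 0 of 8 (1.66, 0.975 and 1.36 matched), and epididymis and germ cell markers 2, 1 and 2 of 10 (1.504, 0.917 and 1.27). Markers of tissues outside the fat pad gave 1, 1 and 1 of 9 for liver (1.90, 1.05 and 1.55 matched), 0, 1 and 0 of 9 for skeletal muscle (1.63, 0.808 and 1.26), 2, 3 and 4 of 12 for neurons (4.50, 3.18 and 4.73) and 0, 0 and 1 of 14 for olfactory and vomeronasal receptors (2.29, 1.37 and 2.20).

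**Figure D2:**
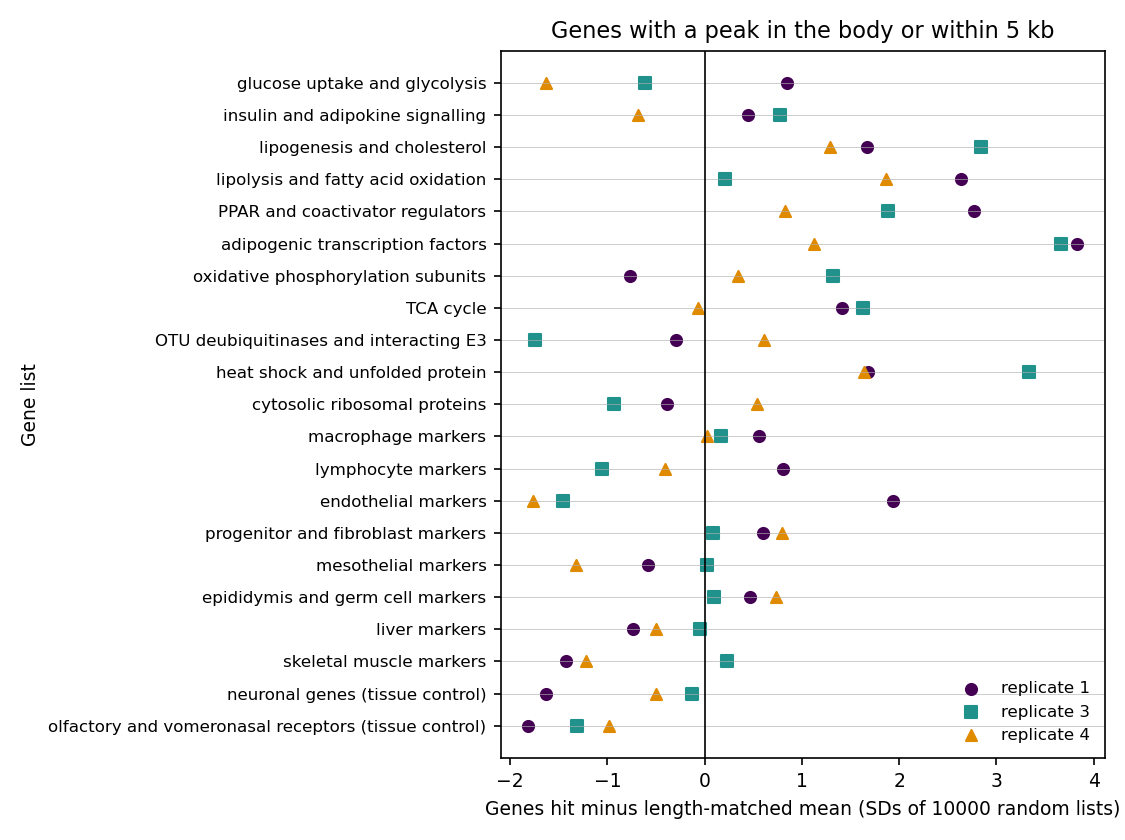
Number of genes of each fixed list with a peak in the gene body or within 5 kb, minus the mean of 10000 random lists matched on gene length, in SDs of those lists (horizontal axis), for the 21 lists (vertical axis) and the 3 libraries (circles, replicate 1; squares, replicate 3; triangles, replicate 4). Adipogenic transcription factors stand 3.83 and 3.67 SDs above the matched lists in replicates 1 and 3 and 1.13 in replicate 4.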

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

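No paired analysis was possible because the input libraries were not analysed here and 1 group remained. The settings leaving out the shared blocks and all of those on adipogenic transcription factors were chosen after seeing the data; the cause of each change was not tested beyond the fewer peaks that a stricter setting leaves. Peaks numbered 10, 7 and 26 at a q of at most 1e-05 and 31, 9 and 17 at a fold of at least 5. Regions in all 3 lists became 3 at that q, 0 at that fold, 49 to 67 without 1 replicate and 142 in at least 2 lists; outside the blocks, which were drawn around these regions, the count is 0 by construction. Regions of at least 2 lists became 11 at that q, 0 at that fold, 78 with 50% reciprocal overlap and 64 with summits within 100 bp. The gene-end share of regions in all 3 lists, 0% of 12 against 3.63% expected, turned to 5.19% against 3.47% for at least 2 lists and was 2.17% to 8.33% without 1 replicate, none past the threshold; at a fold of at least 5 no region was left. Gene ends had 0% of peaks in replicates 1 and 3 at a q of at most 1e-05 (10 and 5 peaks), 0% of 9 peaks in replicate 3 at a fold of at least 5, and in replicate 1 at that fold 19.4% of 31 peaks against 3.48% expected. With placement within 50 kb the expected share passed the 4.11% of replicate 3 and put the 3.00% of replicate 4 below chance, while a 3 kb window with placement on the chromosome put replicate 4 above it (9.13% against 8.40%, permutation p = 0.006). With both changed, chosen after seeing the data, replicate 1 stayed above (15.3% against 13.2%), replicate 3 did not pass (12.3% against 11.9%) and replicate 4 lay below (10.04% expected). At gene ends, 0 fixed lists passed with regions of at least 2 lists, 1 replicate left out or each library alone. The regions of all 3 lists touch no gene, so they and the settings that keep them could give only 0. For adipogenic transcription factors, adjusted p was lost in replicates 1 and 3 at gene ends (3 and 1 genes, 0.7996 and 0.309 expected), with placement within 50 kb (15 and 12 genes, 12.1 and 9.34 expected) and in the peaks above the median fold (10 and 6 genes, 4.72 and 3.21 expected), in replicate 3 with the gene body alone (10 genes, 4.96 expected), and over all 126 tests (permutation, adjusted p = 0.0504 and 0.0882). Replicate 4, not past the threshold in any setting, lay below expectation at gene ends (0 genes) and with placement within 50 kb (10 genes). The calls of replicates 1 and 3 held with matching on gene length and gene density (permutation, adjusted p = 0.0042 and 0.0336). Motifs, CpG matching and the repeat mask were not run. Medians of 4 to 6 fragments per peak limit the results outside the regions of all 3 lists. Those regions had medians of 363 to 409 fragments but folds of only 1.27 to 1.85. All but the scaffold region lay in commonly masked stretches, so their coverage is no evidence of binding.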

Other observations

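The test of further immediate-early genes and the placement tests within 50 kb were set up before their results were seen. The tests of gene density and of the Poisson share on chromosome X and of ribosomal and oxidative phosphorylation genes were chosen after the values they use had been seen.

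Immediate-early genes, which are transcribed within minutes of a stimulus or of tissue handling, carried peaks at their ends in replicates 1 and 3. The 5 first noticed were Junb, Klf4, Dusp1, Zfp36 and Ppp1r15a, and 34 others were then listed without looking at their peaks. Among the 34, Jun belongs, like Junb and Ppp1r15a, to the 83 genes with a region of 2 lists counted above. A shared region of replicates 1 and 3 also lay 2.70 kb from Socs3, another of the 34. Peaks of Jun and peaks near Socs3 may therefore not have been wholly unseen. Of these 34, 8 had a peak within 1 kb of a gene end in replicate 1 (Atf3, Btg2, Egr1, Jun, Jund, Klf6, Klf9 and Nfkbia), against 1.36 expected from all genes (Fisher's exact test, two-sided, p = 4.55e-05, adjusted p over the 3 libraries 6.82e-05). In replicate 3, 6 had one (Btg2, Egr1, Egr2, Ier2, Maff and Socs3), against 0.525 expected (exact p = 1.21e-05, adjusted p = 3.63e-05). In replicate 4 it was 1, Jun, against 0.774 expected (exact p = 0.543), and the difference between libraries was not tested. Btg2 and Egr1 were the 2 hit in both replicates 1 and 3.

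Ribosomal protein and oxidative phosphorylation genes stood in for broadly and highly expressed genes. The comparison was chosen after their counts had been seen. It does not decide whether the ends of highly expressed genes are preferred in general. These genes had 3 of 99 hit at an end in replicate 1 and 4 of 99 in replicate 3. Both shares were lower than those of the immediate-early genes (Fisher's exact test, two-sided, p = 0.000826 and 0.0178). In replicate 3 all 4 were oxidative phosphorylation genes (4 of 59, 0.911 expected from all genes, Fisher's exact test, unadjusted p = 0.0131). Ribosomal proteins had 0 of 40 there. Immediate-early genes were not tested against either set apart, and expression was not measured. Peak-rich surroundings stay open: random placement within 50 kb gave 3.91 genes in replicate 1 and 1.77 in replicate 3 (permutation, two-sided, p = 0.0699 and 0.014). Recovery of open chromatin without binding of the tagged protein also stays open, since the input libraries were not analysed here and there was no library without the tag. No biological explanation was tested, as 1 group was measured.

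For the adipogenic transcription factor genes hit in replicates 1 and 3, surroundings rich in peaks and peaks on the genes themselves cannot be told apart. Placing peaks within 50 kb can keep a hit on long genes, such as the 7 of 71.8 to 541 kb hit in all 3 libraries. This may lower the power of the test to separate the 2, which was not measured, and the question stays open. Placement within 50 kb gave 12.1 genes in replicate 1 and 9.34 in replicate 3, against 15 and 12 observed (permutation, two-sided, unadjusted p = 0.0719 and 0.034).

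Chromosome X held few peaks. Replicates 1, 3 and 4 had 70, 9 and 57 there, or 0.424, 0.0545 and 0.345 intervals per Mb against 4.91, 2.71 and 5.59 on the autosomes, so that the highest ratio of the 3 was 0.0863. Low gene density is argued against as the whole cause, since X lay at −7.00, −6.83 and −12.9 residual SDs from the line of peaks on gene density over the autosomes. A candidate explanation is that nearly all calls sit close to the detection limit on a chromosome present once per cell, as in male tissue such as the epididymal fat pad. For background positions a Poisson tail at 0.5 of the mean predicts ratios of 0.145, 0.0504 and 0.0868 at the lowest number of fragments called and 0.0734, 0.0256 and 0.0441 at the median number, beside 0.0863, 0.0201 and 0.0618 observed. The predictions hold for peaks at the lowest background, 32.3%, 20.7% and 28.8% of the lists of replicates 1, 3 and 4. The observed ratios use all intervals. The comparison does not separate chance pile-ups from weak binding, which would also lose calls on X.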
